A study of Mus musculus with 6 samples.

How the data were processed

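RNA of 6 samples of sorted type II pneumocytes was analysed, 3 heterozygous for Trf2 and 3 with Trf2 deleted, each collected 7 days after tamoxifen. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was isolated from the sorted cells with a column kit, amplified with a NuGEN Pico whole-transcriptome kit, labelled with biotin and hybridised to 1 array per sample. The deposited values are log2 expression levels of 115830 probe sets, computed with RMA in Partek per the submitters' processing notes. As commonly run, RMA corrects the background, normalises the arrays by quantiles and summarises the probes of a probe set. The genome build named in the submitters' processing notes is mm9, and no coordinates were used. The versions of RMA and Partek are not given in the sources used here. Scanner files were not used here, so background correction and normalisation were not repeated from the start, and no limit of detection can be given for single probe sets. The values ran from 0.947 to 13.3 on the log2 scale, and array quartiles lay close together: the lower ones between 2.66 and 2.71, the upper ones between 5.47 and 5.50.

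Probe sets were named through the platform's annotation table. Of them 25539 carried 1 gene symbol, 2300 carried several and 87991 were unnamed in it. Symbols were checked through their Entrez identifiers against a table of mouse RefSeq genes, in which 24941 (97.7%) of the single-symbol probe sets had a match, and 0 symbols changed. A gene was represented by its brightest probe set over all 6 arrays, which mattered for 3109 genes with several, and this left 20259 genes. Probe sets that were unnamed or carried several symbols were tested separately and are given in the additional observations. Many well-known genes were therefore not analysed here under their names. No filter was set on dim genes.

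Deleted and heterozygous samples were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, no covariates). Standard errors of differences between groups are limma's moderated ones (4 residual and 2.96 prior degrees of freedom), and p-values were adjusted by Benjamini and Hochberg's method over the 20259 genes, with a threshold of 0.05. Differences are deleted minus heterozygous, on the log2 scale. A looser count took genes at an unadjusted p under 0.05 with at least 1.5-fold difference. With 3 against 3 samples an exact permutation test of a single value cannot go below 0.1, so such tests were used only for the means of gene lists. The labels call the samples biological replicates. The replicate numbers recur in both groups and were used as a block only in an alternative fit.

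Before the data were examined, 29 gene lists were fixed from general knowledge of lung cell types, telomere biology, p53 signalling, senescence, inflammation, metabolism and tissue handling. They held 605 genes, of which 542 were measured, and the 27 lists with at least 5 measured members were tested with limma's camera, two-sided, with a preset correlation between genes of 0.01 and adjustment over the lists. The same lists were run with a correlation estimated per list and with fry. Of the 9 lists that passed with the preset correlation, 1 passed with an estimated one, and 1 passed with fry in 1 direction. The fry test of change in either direction passed for 5 lists. A member of a list was also tested with adjustment over the list alone.

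The genes named in the text were set by a rule fixed at the same time. It took the genes past the threshold whose groups do not overlap, up to 15 in each direction, and filled a direction with fewer than 10 to 10 genes by the smallest p among those whose groups do not overlap. Predicted genes without a common name were passed over. It added Terf2 and the other telomere genes, Sftpc, Cdkn1a, Mdm2 and Cdkn2a, and in each list the members past the threshold or otherwise the 2 of smallest p. Other members of the p53 list and Mki67 were named after their values were seen.

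Alternatives to this processing were a replicate block, leaving out each array in turn, only genes above the median level, quantile normalisation applied again, arrays centred on their medians, an offset of 32 on the linear scale before log2, the mean of all probe sets of a gene, every probe set on its own, eBayes with trend and robust settings, array weights, no moderation of variances and, for lists, the estimated correlation, fry and ranks. After the data were seen, the p53 list was also run without Phlda3 and without members that another list holds, and the lists that passed fry in either direction were run with each array left out and without the members that passed over the list alone. The procedure was tested on simulated data with the real genes' means, limma's moderated variances and independent noise for each gene. In these data 200 of 20259 genes were changed. The procedure recovered 91 of 100 genes changed by a log2 difference of 1 and 100 of 100 changed by 2, and called 12 unchanged genes. Moderated variances are drawn towards a common value, so these shares need not hold for the real genes. In a simulation of the lists with independent noise for each gene, 0 of 27 were called with no change present. The p53 list raised by 0.5 was called with 0 others. Genes within the real lists are correlated (estimated correlation 0.546 for cell cycle genes), so this gives no rate of false calls for them. Figures were drawn with matplotlib 3.10.9.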

Results

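Gene expression was measured in type II pneumocytes of the adult mouse lung, the alveolar epithelial cells that make and secrete surfactant. The mice carried a Cre recombinase that tamoxifen activates in cells expressing surfactant protein C (Sftpc), together with the mTmG reporter, in which recombined cells switch to green fluorescence. Green cells were collected by sorting 7 days after tamoxifen. In 3 control samples 1 allele of Trf2 was conditional, which left the cells heterozygous, and in 3 samples both alleles were conditional and Trf2 was deleted. Trf2, listed on the array under its symbol Terf2, is a protein of the shelterin complex that caps chromosome ends. Each sample was hybridised to 1 array and is a labelled biological replicate, so that n = 3 in each group throughout. Array medians lay between 3.75 and 3.79 on the log2 scale. Correlations of the arrays over genes were 0.985 to 0.987 within groups and 0.984 to 0.986 between groups. The number of arrays limits the precision of all values below.

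The comparison of deleted with heterozygous cells addressed which transcripts differ in type II pneumocytes after loss of Trf2. Targets of the transcription factor p53 were higher in the deleted cells, led by Phlda3, a p53-induced inhibitor of Akt signalling, and by Cdkn1a, which encodes the cell cycle inhibitor p21. Phlda3 had a mean log2 level of 5.92 ± 0.07 (SD, n = 3) in heterozygous cells and 7.50 ± 0.06 in deleted cells, 2.99-fold higher. Cdkn1a had 8.21 ± 0.12 and 9.85 ± 0.27, 3.13-fold higher. Surfactant protein C itself was near the top of the measured range in both groups, with Sftpc at 12.26 ± 0.09 and 12.17 ± 0.07.

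In its brightest probe set Terf2, the targeted gene, was lower on all 3 deleted arrays than on any heterozygous array. Its heterozygous values were 4.90, 5.39 and 4.80, and its deleted values were 3.75, 3.85 and 3.60. The log2 difference of Terf2 was -1.30 (SE 0.16), which put the heterozygous level 2.46-fold above the deleted one. This passed limma's test adjusted over the 21 genes of telomere maintenance alone (Benjamini-Hochberg adjusted p = 0.00206), but not over all genes (adjusted p = 0.221). With 1 array left out the adjusted p over the list alone was at most 0.0135. A second, dimmer probe set of Terf2 differed by -0.06 between the groups. It had 3.28, 4.06 and 3.18 on heterozygous arrays and 4.38, 2.87 and 3.08 on deleted ones, highest on deleted replicate 1. With the mean of both probe sets the difference was -0.68 (limma adjusted p = 0.797 over all genes). Which exons each probe set covers, and which exons were removed, is not given in the sources used here. Terf2 was the 1 member of the telomere list that fell with adjustment over the list alone, and the other 20 did not pass. Among the shelterin genes, Terf2ip differed by -0.28 (SE 0.09), Terf1 by -0.21 (SE 0.07), Tinf2 by -0.16 (SE 0.09), Pot1a by -0.05, Pot1b by -0.12 and Acd by 0.18 (SE 0.07). The telomerase and accessory genes Tert (-0.06), Dkc1 (-0.16), Nop10 (0.13), Nhp2 (-0.10), Gar1 (-0.21), Naf1 (-0.03), Wrap53 (0.09) and Parn (-0.12) had differences between -0.21 and 0.13. The remaining members were Rtel1 (-0.08), Ctc1 (0.01), Stn1 (-0.05), Ten1 (0.04), Tnks (0.21) and Dclre1b (0.22). The sign of the difference in Ctc1 turned when each array was centred on its median, and those of Tert, Nhp2, Ctc1, Ten1 and Naf1 turned when single arrays were left out. The list of 21 genes includes the deleted gene Terf2 itself, which lowers its mean. With Terf2 included the mean difference was -0.10, the median -0.06, and limma's camera test gave an adjusted p of 0.0766. With 1 array left out it ranged from 0.0337 without deleted replicate 3, which passes, to 0.308 without heterozygous replicate 3. Limma's fry test of change in either direction gave the list an adjusted p of 0.00974, which became 0.0538 without Terf2 and 0.0507 without deleted replicate 1.

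Of 33 p53 target genes in the list, 30 were measured, and 24 of them were higher in the deleted cells. Adjusted over the list alone 16 rose and 0 fell, and 14 did not pass. With 1 array left out, between 13 and 16 rose. Over all 20259 genes tested 1 rose, which was Phlda3 (log2 difference 1.58, SE 0.08, limma with Benjamini-Hochberg adjusted p = 0.00437). The genes that rose with adjustment over the list alone included Dglucy, a mitochondrial D-glutamate cyclase (1.49, SE 0.12), Cdkn1a (1.65, SE 0.15), Ccng1, which encodes cyclin G1 (1.13, SE 0.11), Trp53inp1 (1.03, SE 0.13) and Psrc1 (1.58, SE 0.21). Over all genes their limma adjusted p-values were 0.0550 for Dglucy, 0.0660 for Cdkn1a, 0.0720 for Ccng1, 0.226 for Trp53inp1 and 0.246 for Psrc1. Also among the 16 were the apoptosis-enhancing nuclease Aen (0.92), Ddit4l (1.06), the RNA-binding protein gene Zmat3 (0.82), the translesion DNA polymerase gene Polk (0.51), Dcxr (0.58), the stress-induced sestrin Sesn2 (0.45), the antiproliferative gene Btg2 (0.37) and Plk2 (0.44). The death receptor genes Tnfrsf10b (0.66) and Fas (0.34) completed them. With 1 array left out, Plk2 kept its call only without heterozygous replicate 3, and Btg2 only without heterozygous or deleted replicate 2. Fas lost its call without deleted replicate 2 or 3, and Sesn2 without deleted replicate 1. The rest of the 16 kept theirs each time. Mdm2, which encodes the ubiquitin ligase that removes p53, was 6.68 ± 0.16 in heterozygous and 6.95 ± 0.12 in deleted cells. With all arrays its difference of 0.27 (SE 0.11) passed neither adjustment, but it passed over the list alone without heterozygous replicate 1. Bbc3 (0.15), Perp (0.19), Sesn1 (-0.08), Rrm2b (-0.21) and Pmaip1 (-0.04) were among the 14 that did not pass. Bax, Gdf15 and Ei24 had no probe set of a single symbol and were not analysed here.

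As a group the p53 targets rose by a mean of 0.52 on the log2 scale (SE over arrays 0.031; median 0.36). The list's mean level lay between -0.28 and -0.24 on the heterozygous arrays and between 0.20 and 0.31 on the deleted arrays. The camera test of limma gave the list an adjusted p of 2.04e-20 over 27 lists, and adjusted p = 0.0236 with an estimated correlation. The rotation test fry, also from limma, gave an adjusted p of 0.00173. An exact two-sided permutation test of the list's mean gave p = 0.1, the smallest that 3 arrays against 3 allow.

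**Figure D1:**
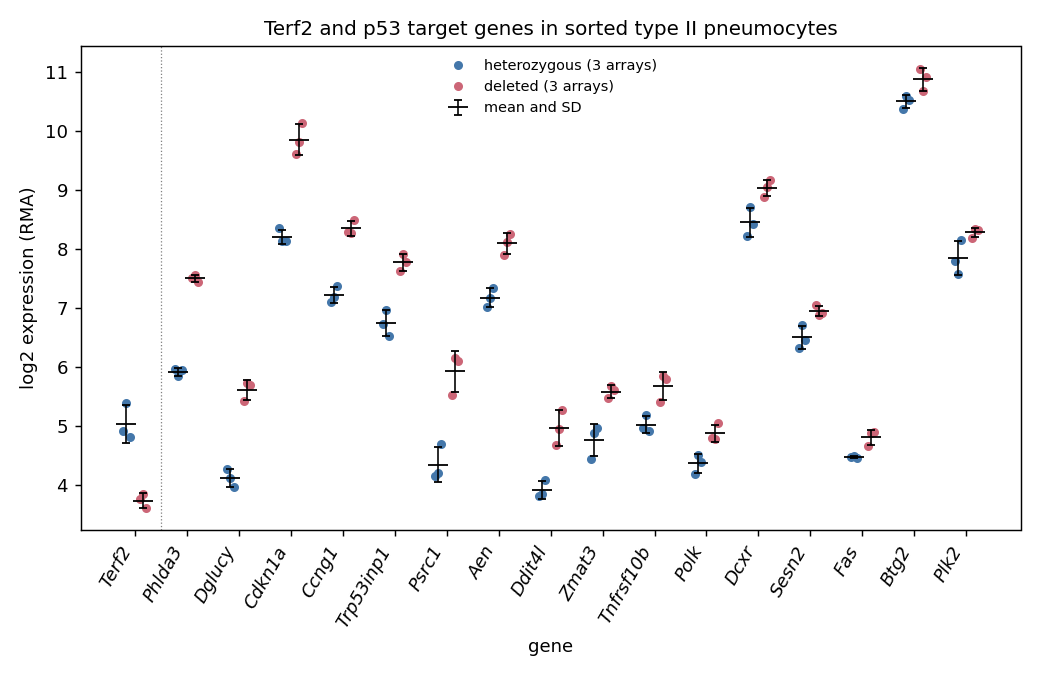
Expression of Terf2 and of the 16 p53 target genes that rose with adjustment over the list alone, in log2 units (vertical axis), by gene (horizontal axis). Each point is 1 array, blue for heterozygous and red for Trf2-deleted cells, and the black marks give the mean and SD of 3 arrays. For Phlda3 the heterozygous mean of 5.92 and the deleted mean of 7.50 stand apart by far more than the SDs of 0.07 and 0.06, and the brightest probe set of Terf2 lies lower on all 3 deleted arrays.

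Outside the p53 list, the genes with the smallest p-values among those higher in deleted cells were Ephx1, Phf10, Sh3bgrl2 and Ddias. Ephx1, the microsomal epoxide hydrolase, was 6.89 ± 0.13 in heterozygous and 7.90 ± 0.11 in deleted cells (limma adjusted p = 0.0875). Phf10, a subunit of a chromatin remodelling complex, differed by 0.99 (SE 0.12), Sh3bgrl2 by 0.89 (SE 0.11) and Ddias, named for suppression of apoptosis after DNA damage, by 1.11 (SE 0.15). None of these 4 passed the threshold over all genes. Besides Terf2, the genes of smallest p among those lower in deleted cells were Uba6, a ubiquitin-activating enzyme (-0.64, SE 0.08), the zinc finger gene Zfp951 (-0.49, SE 0.07), Wls, which is needed for Wnt secretion (-0.60, SE 0.09), and the amino acid transporter Slc6a20a (-1.03, SE 0.16). They were followed by Klhl25 (-0.54), Asb17 (-0.42), the aldehyde oxidase Aox3 (-0.56), the circadian transcription factor Npas2 (-1.10, SE 0.20) and Plac8 (-0.62). None of these passed either: limma's adjusted p was 0.187 for Uba6 and 0.617 for Plac8. The rule that named the genes in this paragraph required groups that do not overlap and passed over predicted genes. Groups did not overlap for 2312 of all genes (11.4%), where chance gives 10% for 3 arrays against 3.

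Over all genes, limma called 1 gene higher and 0 lower at an adjusted p under 0.05, and 5 higher at an adjusted p under 0.1 (Phlda3, Dglucy, Cdkn1a, Ccng1 and Ephx1). At an unadjusted p under 0.05 there were 1243 genes, where 1013 would pass by chance. With a fold of at least 1.5 in addition there were 190, of which 96 were higher and 94 lower in deleted cells. The count of 1 became 0 with no moderation of variances (Phlda3 adjusted p = 0.0620), and in limma when heterozygous replicate 1 (adjusted p = 0.0529) or 3 (0.0635) or deleted replicate 1 (0.0511) or 2 (0.0645) was left out. The count was also 0 with the replicate number as a block (Phlda3 limma adjusted p = 0.286) and with every probe set on its own. It became 5 when only genes above the median level were tested, and 2 or 3 in some other settings.

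Cell cycle genes were lower as a group in the deleted cells, with 34 of 39 measured members lower and a mean difference of -0.42 (SE over arrays 0.21). The mean level of these genes stood apart on 1 array, heterozygous replicate 3, at 0.62, against 0.04 and -0.03 on the other heterozygous arrays and -0.24 to -0.16 on the deleted arrays. Without that array the mean difference was -0.21, and Mki67 and Top2a fell with adjustment over the list alone. The proliferation marker Mki67 was 4.87 ± 0.95 in heterozygous and 3.56 ± 0.17 in deleted cells, Top2a, a DNA topoisomerase of dividing cells, 4.21 ± 0.59 and 3.16 ± 0.07, and the spindle checkpoint kinase Bub1b 4.85 ± 0.15 and 4.44 ± 0.17. With all arrays 0 members passed over the list alone, and 13 fell when heterozygous replicate 2 was left out. The camera test of limma gave the list an adjusted p of 1.30e-12, but adjusted p = 0.451 with an estimated correlation, and fry gave 0.362.

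DNA damage and repair genes had 21 of 29 members lower (mean -0.06), with limma's camera adjusted p = 0.0376, and adjusted p = 0.553 with an estimated correlation. Without heterozygous replicate 3 it was 0.465 and without deleted replicate 1 it was 0.330, and it was 0.547 with only genes above the median level. The checkpoint kinase Chek1 was 3.86 ± 0.10 in heterozygous and 3.53 ± 0.06 in deleted cells, and the histone gene H2ax 5.44 ± 0.06 and 5.25 ± 0.01. Macrophage markers had 17 of 22 members lower (mean -0.25), including Ptprc (-0.59, SE 0.16), the leukocyte antigen CD45, and the integrin Itgam (-0.35, SE 0.10). Limma's camera test of the macrophage list gave an adjusted p of 5.26e-05, and adjusted p = 0.426 with an estimated correlation. Its highest mean level, 0.31, was on heterozygous replicate 3, the array with the highest cell cycle level, and without that array the mean difference was -0.16 (limma's camera adjusted p = 0.0108). Neutrophil markers had 11 of 13 members lower (mean -0.14), among them S100a8 (-0.52, SE 0.22) and Trem1 (-0.38, SE 0.12), with limma's camera adjusted p = 0.0376, and adjusted p = 0.479 with an estimated correlation. Their call was lost without heterozygous replicate 1 (adjusted p = 0.193) or 3 (0.0596) and without deleted replicate 2 (0.242) or 3 (0.0753). Interferon response genes had 21 of 30 members lower (mean -0.13), with the chemokine Cxcl10 at -0.65 (SE 0.16) and Xaf1 at 0.36 (SE 0.16). Their camera adjusted p in limma was 0.0447, and adjusted p = 0.622 with an estimated correlation. Without heterozygous replicate 3 camera's direction, which is relative to all other genes, turned (adjusted p = 0.990). The mean difference of the list was then -0.03, still lower in deleted cells. Without heterozygous replicate 1 the camera adjusted p was 0.0630, and without deleted replicate 1 or 2 it was 0.0891 or 0.0838.

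Genes of lipid and surfactant synthesis had 25 of 34 members lower in deleted cells (mean -0.09), with limma's camera adjusted p = 0.00842, and adjusted p = 0.426 with an estimated correlation. Without heterozygous replicate 1 or 3 the adjusted p was 0.0624 or 0.0596. Acaca, which makes malonyl-CoA for fatty acid synthesis, was 8.60 ± 0.10 in heterozygous and 8.26 ± 0.18 in deleted cells, and Idi1 of the cholesterol pathway 8.89 ± 0.17 and 8.56 ± 0.10. Type II cell markers had 18 of 22 members lower by small amounts (mean -0.05, SE over arrays 0.027), including Bex2 (-0.24) and Hc (-0.23), and did not pass (limma's camera adjusted p = 0.0645), but passed without deleted replicate 3 (0.0218). Ciliated cell markers had 13 of 15 members higher (mean 0.15), such as Ccdc113 (0.26) and Fam183b (0.44). Both were dim, with group means near or below the array medians of 3.75 to 3.79. Fam183b was 4.22 on deleted replicate 1 and 3.57 on each other deleted array. Without deleted replicate 1 the mean difference of the ciliated list was 0.10, and it still passed (limma's camera adjusted p = 0.0101). Club cell markers had 10 of 12 members higher (mean 0.10), such as Scgb1c1 (0.25) and Krt15 (0.20). Limma's camera test gave ciliated markers an adjusted p of 0.000426 and club markers 0.0180, and with an estimated correlation each had adjusted p = 0.426. The club list also missed the threshold without heterozygous replicate 3 (adjusted p = 0.110) or deleted replicate 1 (0.0884). No member of these 4 lists passed with adjustment over its list alone. In all, 9 of 27 lists passed with the preset correlation, 3 higher and 6 lower. The p53 list was the 1 that passed with an estimated correlation, and without heterozygous replicate 3 the 9 became 4.

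The other lists did not pass the camera test with all arrays. Of these, besides the telomere list, limma's fry test of change in either direction passed for the genes secreted by senescent cells (adjusted p = 0.0104), the Krt8 transitional genes (0.000597) and the unfolded protein response (0.0442). Without Cdkn1a the adjusted p was 0.855 for the secreted genes and 0.295 for the transitional genes. With 1 array left out it ranged from 0.00218 to 0.494 for the secreted genes, 0.00253 to 0.0148 for the transitional genes and 0.0165 to 0.572 for the unfolded protein response. Genes secreted by senescent cells had 15 of 36 members higher, with a mean of 0.002, a median of -0.03 and a camera direction of lower (limma's camera adjusted p = 0.426). In that list Cdkn1a rose with adjustment over the list alone, Il1b differed by -0.77 (SE 0.27), and Cdkn2a, which encodes the senescence marker p16, was 4.99 ± 0.04 in heterozygous and 5.17 ± 0.15 in deleted cells. The list passed as lower without deleted replicate 1 (adjusted p = 0.0418), and its direction turned without deleted replicate 3. Inflammatory genes driven by NF-kB had 21 of 31 members lower (mean -0.09, limma's camera adjusted p = 0.0645), with Nfkbie at -0.50 (SE 0.15), and passed without heterozygous replicate 2 (adjusted p = 0.00810) or deleted replicate 1 (4.05e-06). Apoptosis genes had 13 of 24 members higher (mean 0.08; limma's camera adjusted p = 0.0948). Genes of the transitional state between type II and type I cells, marked by Krt8, had 8 of 18 members higher, with a mean of 0.04, a median of -0.04 and a camera direction of higher (limma's camera adjusted p = 0.833). Cdkn1a was again the 1 member that rose with adjustment over the list alone, and the integrin Itgb6 differed by -0.30 (SE 0.09). In the list of TGF-beta and fibrosis genes (13 of 21 higher; limma's camera adjusted p = 0.426), the matrix protein gene Tgfbi rose in limma's test by 0.67 (SE 0.13) with adjustment over the list alone (adjusted p = 0.0327), but not without heterozygous replicate 2 (0.140) or 3 (0.150) or deleted replicate 1 (0.144) or 3 (0.140). Antigen presentation genes had 11 of 12 members lower (mean -0.07, limma's camera adjusted p = 0.110), with Erap1 at -0.17 and Tap2 at -0.10. The antigen presentation list passed without heterozygous replicate 1 (0.0442) or deleted replicate 3 (0.0305), and its adjusted p was 0.960 without deleted replicate 1. The mean difference was -0.06 for mitochondrial respiration genes (Ppargc1b -0.63, SE 0.23; Uqcrfs1 0.25, SE 0.11) and -0.05 for genes of the unfolded protein response (Hyou1 -0.28, SE 0.08; Pdia6 0.21, SE 0.09). Limma's camera adjusted p was 0.124 for mitochondrial respiration and 0.224 for the unfolded protein response. Genes induced by handling and dissociation of tissue had a mean of 0.02, a median of -0.04 and a camera direction of lower (limma's camera adjusted p = 0.426), with Egr1 at -0.30 (SE 0.09).

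Markers of the remaining cell types gave limma camera adjusted p-values of 0.0766 for mesenchymal cells, 0.287 for B cells, 0.326 for T and NK cells and for basal cells, 0.426 for mesothelial cells, 0.541 for endothelial cells and 0.795 for type I cells. Of mesenchymal markers 14 of 15 were higher (mean 0.10, SE over arrays 0.14), such as Col6a1 (0.36) and Col1a2 (0.15). Without deleted replicate 3 the mesenchymal list passed (limma's camera adjusted p = 3.22e-05), while without deleted replicate 1 its adjusted p was 0.576. Mesothelial markers passed as higher without deleted replicate 3 (adjusted p = 0.0146) and type I markers as lower without deleted replicate 1 (0.0101). The B cell factor Ebf1 rose by 0.82 (SE 0.20) with adjustment over the list alone (limma adjusted p = 0.0447), but not without heterozygous replicate 1 (0.105) or any of the deleted replicates (0.178, 0.174 and 0.0611), and Blk differed by 0.11. T and NK cell genes included Nkg7 (-0.37) and Cd3e (0.31), type I markers Aqp5 (0.23) and Emp2 (0.13), and endothelial markers Calcrl (-0.22) and Ramp2 (-0.18). Mesothelial Upk1b differed by 0.26 and Lrrn4 by 0.16, and basal Krt5 by -0.18 and Krt14 by -0.14. Too few erythroid genes were measured for a test of that list, and Alas2 differed by 0.61 (SE 0.39) and Slc4a1 by 0.07, values set by deleted replicate 1, without which they were 0.10 and -0.08. Among sex chromosome genes, Xist lay between 3.02 and 3.47 and the Y-linked Kdm5d between 5.25 and 5.39 on the 6 arrays.

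**Figure D2:**
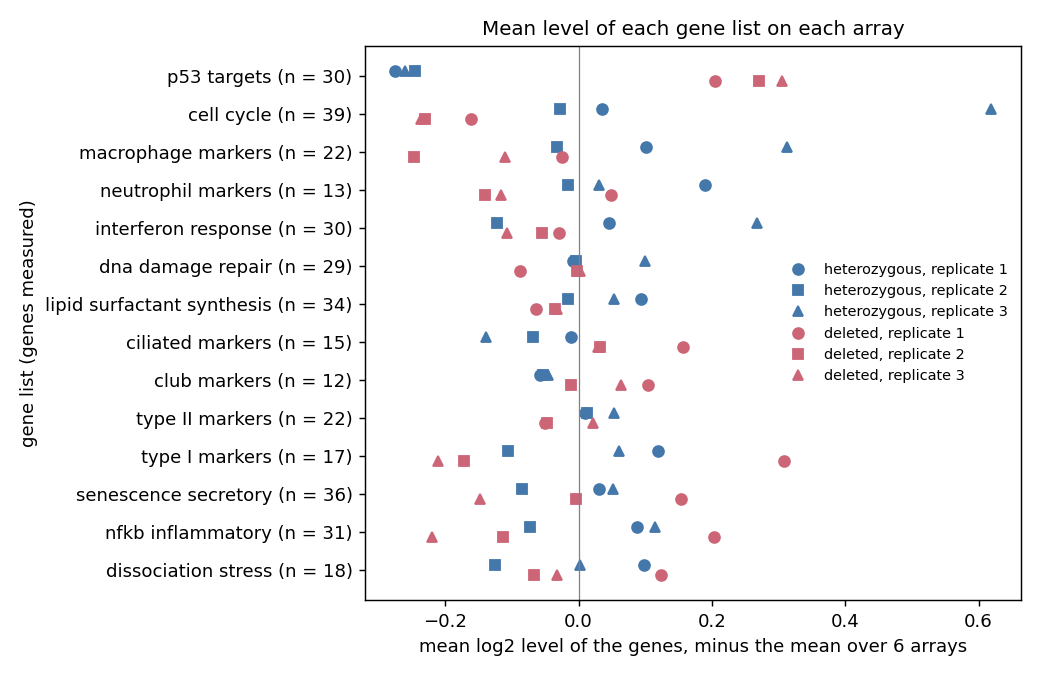
Mean log2 level of the genes of 14 lists on each of the 6 arrays (horizontal axis, relative to the mean over the arrays), by list (vertical axis, with the number of genes measured). Blue symbols are heterozygous and red symbols deleted cells, and symbol shapes give the replicate. The p53 targets lie between -0.28 and -0.24 on heterozygous and between 0.20 and 0.31 on deleted arrays, and the cell cycle genes stand at 0.62 on heterozygous replicate 3.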

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

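The group difference in p53 targets kept its direction and its side of the threshold in each alternative that was run. Its adjusted p in limma's camera was 0.0236 with an estimated correlation, and in the runs chosen after seeing the data it was 0.0438 without Phlda3 and with an estimated correlation, and 0.0167 without members shared with another list and with an estimated correlation. The probe set that represents Terf2 was lower in deleted cells in each alternative that gave it a value, from -1.42 without heterozygous replicate 3 to -0.52 with the offset. The offset pulls differences of dim genes towards 0, and the mean of both Terf2 probe sets gave -0.68. On its own the second Terf2 probe set differed by -0.06, and its highest value, 4.38, was on deleted replicate 1. Terf2 lies below the median level, so the test of genes above it gave no value, nor did it for lists left with fewer than 5 members. Across named genes and lists, 1338 gene values and 361 list values kept direction and side of the threshold. Only Phlda3 passed it in the main fit, so for most named genes keeping their side says little. Genes named for groups that do not overlap also cannot change direction when an array is left out. Of the other gene values 6 fell short of the threshold, all of them of Phlda3, 9 newly passed it and 11 changed direction. Of the other list values 40 fell short, 14 newly passed and 16 changed direction. Except where stated, the cause of a change was not tested.

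The 1 gene past the threshold became 5 with only genes above the median level (fewer genes are then tested), 3 with the mean of probe sets, 2 with quantile normalisation again, 2 with trend and robust settings, 2 with array weights, 0 with no moderation, 0 with every probe set on its own (6691 of 115830 at an unadjusted p under 0.05, where chance gives 5%), and 0 to 1 with 1 array left out. With the replicate number as a block it was 0 (Phlda3 adjusted p = 0.286), with 1297 genes at an unadjusted p under 0.05. Deviations from the group means of same-numbered arrays correlated by 0.0953, -0.000594 and 0.00111 for replicates 1, 2 and 3. The first was the highest of all pairs of arrays across groups. Whether the numbers pair the samples is not given in the labels, and these values cannot decide it. The looser count of 190 (50.5% higher) became 100 above the median level (58% higher), 26 with the offset (69.2% higher), which shrinks differences by construction, 92 with no moderation (60.9% higher) and 4191 of all probe sets.

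The alternatives of fry in either direction were chosen after seeing the data, and 2 of its 5 lists, p53 targets and the Krt8 transitional genes, passed with each array left out. The transitional genes did not pass fry in either direction without Cdkn1a (adjusted p = 0.295), a gene that the p53 list also holds. The 9 lists past the threshold became 3 above the median level, 1 with an estimated correlation, 1 with fry and 4 to 13 with 1 array left out, with 4 without heterozygous replicate 3. Interferon genes had camera adjusted p = 0.0564 with the replicate block, 0.345 above the median level, 0.0608 with arrays centred on their median, 0.0513 with the offset, 0.0695 with the mean of probe sets, 0.622 with an estimated correlation, 0.660 with fry and 0.000132 to 0.990 with 1 array left out. The last was without heterozygous replicate 3, where camera's direction was the opposite but the mean difference was still negative (-0.03). DNA damage genes had 0.0564 with the replicate block and 0.547 above the median level, ciliated markers 0.126 and club markers 0.0711 above the median level, and neutrophil markers 0.0520 with the offset. Cell cycle genes had 0.0533 above the median level, 0.451 with an estimated correlation and 0.362 with fry. Mesenchymal markers passed with ranks (0.0336) and ranged from 3.22e-05 without deleted replicate 3 to 0.576 with 1 array left out, antigen presentation genes from 0.0305 to 0.960 and telomere genes from 0.0337 to 0.308. Type II markers passed with the offset (0.00772) and with ranks (0.0353), and ranged from 0.0218 to 0.373 with 1 array left out. NF-kB genes passed with array weights (0.0144) and ranged from 4.05e-06 without deleted replicate 1 to 0.709, and secreted genes of senescence from 0.0418 without deleted replicate 1 to 0.990, with the direction turned without deleted replicate 3.

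Small differences changed sign. The transitional list marked by Krt8 had the opposite camera direction with the replicate block (0.735), array weights (0.947) and ranks (0.856), and ranged from 0.281 to 0.872 with 1 array left out. With 1 array left out, adjusted p also ranged, with both camera directions present, from 0.0556 to 0.990 for endothelial, 0.0101 to 0.933 for type I and 0.0146 to 0.990 for mesothelial markers, and from 0.0620 to 0.968 for TGF-beta genes. Ctc1 was -0.00038 with arrays centred on their median. With 1 array left out, differences ran from -0.0625 to 0.0714 for Ctc1, -0.113 to 0.0411 for Tert, -0.245 to 0.0520 for Nhp2, -0.0282 to 0.0938 for Ten1, -0.155 to 0.0684 for Naf1, -0.401 to 0.0299 for Ramp2 and -0.0779 to 0.155 for Slc4a1. Signal over background could not be given from the summarised values.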

Other observations

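Genes of the circadian clock had mean differences of opposite signs in their opposing arms. The list of these genes and the tests on it were chosen after the result was seen, as were the tests of handling stress, of other cell types and of red blood cells. The 12 measured genes grouped by phase with Dbp were all higher in deleted cells, 7 of them at an unadjusted p under 0.05. Among these, the clock repressor Ciart was 5.39 ± 0.56 (SD, n = 3) in heterozygous and 6.72 ± 0.50 in deleted cells, the transcription factor Dbp 6.83 ± 0.42 and 7.69 ± 0.15, and the period gene Per3 6.08 ± 0.24 and 6.84 ± 0.39. The 4 genes of the opposite phase were all lower, 2 of them at an unadjusted p under 0.05, with Arntl, the core activator of the clock, at 5.47 ± 0.32 and 4.34 ± 0.39, and its binding partner Npas2 at 5.67 ± 0.34 and 4.57 ± 0.26. These directions held in each of the 16 genes when arrays were quantile normalised again, centred on their medians, or given the offset, and with the mean of probe sets. The weight of single arrays was not tested for them. Nr1d1 was 6.27, 7.61 and 7.85 on the deleted arrays, against 6.52, 7.17 and 7.37 on the heterozygous ones. Usp2 was 6.10 on deleted replicate 1 and 4.84 and 4.73 on the other deleted arrays. No clock gene passed limma's threshold over all genes (adjusted p = 0.634 for Arntl and 0.708 for Ciart). Because the genes were chosen for the pattern, a test of them as a group cannot support it, and limma's camera passed for the arm with Dbp with the preset correlation (adjusted p = 5.22e-09) but not with an estimated one (0.378).

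The long noncoding RNAs Rian and Kcnq1ot1 were picked out as single genes after their values were seen, and noncoding RNAs were not tested as a group. Rian was 5.32 ± 0.31 in heterozygous and 6.98 ± 0.67 in deleted cells, and Kcnq1ot1 4.80 ± 0.12 and 5.45 ± 0.19. Neither passed over all genes (limma adjusted p = 0.634 for Rian and 0.617 for Kcnq1ot1). Of 90291 probe sets with no symbol or several, 0 passed limma's threshold, and 5075 had an unadjusted p under 0.05, where chance gives 5% of them. The unnamed probe set 6762440 was higher by 3.20 (SE 0.30) and 6803109 by 2.25 (SE 0.17), while 6808549 differed by -2.08 (SE 0.20) and 7010597 by -2.10 (SE 0.20), each with a limma adjusted p of 0.328. In deleted cells 6808549 had a mean of 1.90 and 7010597 of 2.83, below or near the lower quartiles of the arrays.

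For the clock genes, a loss of activity of the Arntl and Clock proteins would lower their targets. The arm with Dbp had a mean difference of 0.53 (SE over arrays 0.160). Its genes were chosen after their values were seen, so this does not decide the question. The opposite arm had a mean of -0.77 (SE 0.216). Different times of day at harvest in the 2 groups may give opposite arms of this kind, and cannot be told apart from an effect of Trf2 loss, because the labels give no harvest times.

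For the higher p53 targets, handling stress, other cell types and red blood cells in the deleted group are candidate explanations. Their gene lists were fixed before the data were examined. The bounds for these comparisons were set after the values were seen, so they weigh less than planned tests. The 17 stress genes not shared with the p53 list had a mean difference of -0.00486 (SE 0.0918) against 0.52 for the p53 list. This argues against handling stress. More cells of another type in the deleted sorts would need a marker list that is higher by as much. With all arrays the highest mean difference among the 11 tested lists, that of ciliated markers, was 0.146 (SE 0.0556). Macrophage markers were lower (-0.25, SE 0.119). The widest spread was that of mesothelial markers, with a mean of 0.0876 (SE 0.184). Without deleted replicate 3 the mean was 0.234 (SE 0.139) for mesothelial and 0.233 (SE 0.0407) for mesenchymal markers, against 0.498 for the p53 list. These values argue against the tested cell types, least firmly for mesothelial cells. The 3 measured erythroid genes had a mean difference of 0.221 (SE 0.259), but without deleted replicate 1 it was -0.0328 (SE 0.0707) against 0.55 for the p53 list, which argues against red blood cells as the cause. Among the 10 splits of the 6 arrays into 3 and 3, the real one gave a -log10 camera p of 21.1 and the highest of the others 2.71, 1 of the 10 gave a value as large, the real one included, and 10 splits are too few for a share under 0.05. A response of the cells to the loss of Trf2 stays open as a hypothesis.

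For the lower cell cycle genes, leaving out heterozygous replicate 3 kept a share of 0.510 of the mean difference of -0.42, so that this array sets much of the difference but not its direction. Cycling immune cells in some sorts may contribute. Within groups, the cell cycle level of an array went with its macrophage marker level (Pearson r = 0.843, exact permutation p = 0.0556 over 36 permutations within groups), which leaves this open, while sorting for green cells should remove such cells. These explanations and lower proliferation after Trf2 loss cannot be told apart with these arrays.

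For the counts, the 10 splits are too few for a share under 0.05. The real split gave 1 gene past the threshold and the highest of the others 0, so that 1 split gave as many, the real one included. It gave 190 genes by the looser count against 164 at most elsewhere, so again 1. For gene lists it gave 9, and the highest of the others 11, so that 2 of the 10 gave as many.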
